A study of Mus musculus with 8 samples.

How the data were processed

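Single-cell transcripts were measured in Peyer's patches of male C57BL/6J mice in 8 libraries, 1 for each combination of age, diet and DSS, with 3 mice pooled per library, per the labels. Tissue was dissociated with enzymes, red cells were lysed and dead cells were removed with beads, per the labels' protocols. The labels give both all cell types and B cells, so cell classes were set from the data. The deposited files hold UMI counts per gene and barcode, written by Cell Ranger 7.0.0 per the file headers, already restricted to called barcodes. The submitters' processing notes also name Seurat 4.1.0, and the deposited counts are whole numbers with no scaling. The genome build is not given in the sources used here. Each file holds 55357 features. Antigen receptor libraries and other diets are not analysed here.

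Everything that follows was computed from these counts. Python 3.11.15 with scanpy 1.11.5, leidenalg 0.10.2, scikit-learn 1.9.0, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used for cells, and R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 for tests. Barcodes with at least 500 UMIs, at least 250 genes and at most 10% mitochondrial UMIs were kept, which removed 7.14% to 18.8% per library. The lowest UMI count among barcodes in the files differs between libraries, from 500 in 5 of them to 1323 in adult HPD DSS. Doublets were predicted per library from 2 simulated doublets per cell at an expected 0.8% per 1000 cells, which removed a further 5.49% to 7.44%. In the order used in the results, 8370.0, 8647, 7901, 7796, 7052, 8756, 7551 and 8023 cells were left.

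Cells of all libraries were scaled to 10000 UMIs, log transformed and clustered together on 2000 variable genes, 30 principal components and 20 neighbours at resolution 1, giving 37 clusters. No batch correction was applied, as each condition is 1 library. Immunoglobulin, T cell receptor, ribosomal and mitochondrial genes and the members of the response lists tested later (interferon, glycolysis, heat shock and others) were left out of the clustering genes. A cluster was named after the marker list of 13 with the highest score if at least 3 of its markers passed. A marker passed if at least 4-fold above the 25th percentile over clusters, with 10 CPM added, and seen in at least 10% of cells. Clusters 26 and 31 scored highest for the epithelial list but were left unnamed. Cluster 26 had a depth of 0.245 relative to the library median, and cluster 31 had stromal markers among its leading genes. Names end in -like because no sort or protein marker stands behind them.

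Genes were tested on UMI counts summed per library over the cells of a class. edgeR used TMM factors, filterByExpr with a minimum count of 10, a quasi-likelihood fit with age, diet and DSS as additive terms (4 residual degrees of freedom) and Benjamini-Hochberg adjustment, with adjusted p under 0.05 called. The SE printed is the size of the log2 fold change over the square root of F, and none is given where F is about 0. Each interaction was fitted by adding its term to the additive model (3 residual degrees of freedom). A difference that depends on another factor adds to the spread in the additive model. Fixed gene lists (34, of which those with at least 5 tested genes were used) were tested with camera of limma at an inter-gene correlation of 0.01, and again with the correlation estimated, and with fry. Counts adjusted over the list alone use the edgeR p-values of that list's genes. Shares of cells and of IgA among heavy-chain constant-region UMIs were compared by an exact permutation test that flips labels within the 4 pairs of libraries differing in 1 factor, with 16 assignments and a smallest p of 0.125, printed as 0.13. Single pairs of libraries were described by log2 ratios of CPM with exact Poisson intervals, for genes with at least 200 UMIs in the 2 libraries together, and carry no test.

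Named genes follow a rule. Among genes past the threshold with a mean of at least 10 CPM and the same direction in all 4 pairs, the 10 largest changes each way are eligible, without antigen receptor variable genes and unnamed gene models, together with up to 4 members of each list past the threshold, and Pkm and Stat1 in every comparison. In single pairs the 5 highest and 5 lowest ratios, Pkm and Stat1 are eligible. Groups, tests, gene lists, markers, the rule and 17 alternatives, plus leaving out each library, were set before the data were examined. Another 6 alternatives were added after the data had been seen: free RNA subtracted, genes higher in epithelial-like cells left out, at least 1500 UMIs per cell, droplets with 5 or more hemoglobin UMIs left out, shares outside epithelial-like and unnamed clusters, and the minimum of 20 UMIs for interferon targets in single pairs.

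Free RNA was estimated from the epithelial list: its CPM in a class over its CPM in all cells of the library was 1.93% to 5.90% in follicular B-like, 0.692% to 2.44% in GC B-like and 1.03% to 5.05% in T-like cells. To part a change in the mix of clusters from a change within them, each class profile was rebuilt with the cluster profiles fixed, or with the mix fixed.

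The gene and list tests were tested on simulated data with 200 changed genes, 100 at 2-fold and 100 at 4-fold. Recovered shares at 2-fold and 4-fold in follicular B-like cells were 47% and 95% for age, 60% and 98% for diet and 58% and 97% for DSS. In GC B-like cells they were 46% and 91% for age, 52% and 98% for diet and 61% and 94% for DSS, and in T-like cells 61% and 91% for age, 60% and 91% for diet and 63% and 90% for DSS. Interactions were recovered less: 3% and 50% for age by diet, 2% and 40% for age by DSS and 7% and 57% for diet by DSS in follicular B-like cells, and 3% and 25% for age by diet, 1% and 17% for age by DSS and 3% and 42% for diet by DSS in GC B-like cells. All recovered genes had the right direction, but unchanged genes were among those called. For age, diet and DSS these were 6 of 148, 13 of 171 and 22 of 177 in follicular B-like, 11 of 148, 20 of 170 and 24 of 179 in GC B-like and 6 of 158, 11 of 162 and 11 of 164 in T-like cells. For age by diet, age by DSS and diet by DSS they were 9 of 62, 7 of 49 and 21 of 85 in follicular B-like and 4 of 32, 4 of 22 and 9 of 54 in GC B-like cells. These are over 5% of calls except for age in follicular B-like and T-like cells. An adjusted p under 0.05 therefore did not hold false calls to 5%. A changed list was called in each comparison, and of 30 random lists at most 1 was. Simulated genes were drawn independently, so these lists could not show false calls that come from correlation between genes.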

Results

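The data are 8 single-cell libraries of Peyer's patches from male C57BL/6J mice, 1 library per condition, each pooled from 3 mice. The conditions cross age (3 or 11 weeks), dietary protein (20%, SD, or 40%, HPD) and repeated low-dose DSS (none or 3 cycles). All 8 carry the same batch date. Series of 8 values are given in the order juvenile SD, juvenile HPD, juvenile SD DSS, juvenile HPD DSS, adult SD, adult HPD, adult SD DSS and adult HPD DSS. In that order the files hold 9908, 9956, 9847, 9629, 8569, 10569, 9901 and 9966 barcodes, with median depths of 2287, 2023, 2057, 2701, 4073, 3975, 3548 and 2326 UMIs per barcode, and total depth ran from 32984947 UMIs in juvenile SD DSS to 57910779 in adult SD. Because each condition has 1 library, tests compare the 4 libraries of each level of a factor (n = 4 and 4). The p-values of genes, cell numbers and shares measure only the spread between these libraries. Camera p-values compare a list's genes with the other genes, at a preset inter-gene correlation unless an estimated one is stated. At the preset correlation a small p does not measure how far the libraries of a level differ. Values are log2 fold changes ± SE of adult over juvenile, HPD over SD, or DSS over none. CPM values are means ± SD over the 4 libraries of each level.

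Epithelial cells were a large part of these preparations. Epithelial-like droplets, the clusters marked by keratins and other enterocyte genes, made up 13.5%, 13%, 23%, 43.3%, 62.9%, 72.0%, 79.6% and 75% of the cells kept. Follicular B-like cells were 60.2%, 59.7%, 43.8%, 14.0%, 15.3%, 6.88%, 6.69% and 0.486%. Germinal center (GC) B-like cells were 6.30%, 10.0%, 6.28%, 0.680%, 4.35%, 1.96%, 0.318% and 1.10%. T-like cells were 17.2%, 15.0%, 24.0%, 39.6%, 11.6%, 15.6%, 10.4% and 17.3%. The numbers of follicular B-like cells ran from 5160 in juvenile HPD to 39 in adult HPD DSS, and those of GC B-like cells from 867 in juvenile HPD to 24 in adult SD DSS.

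**Figure D1:**
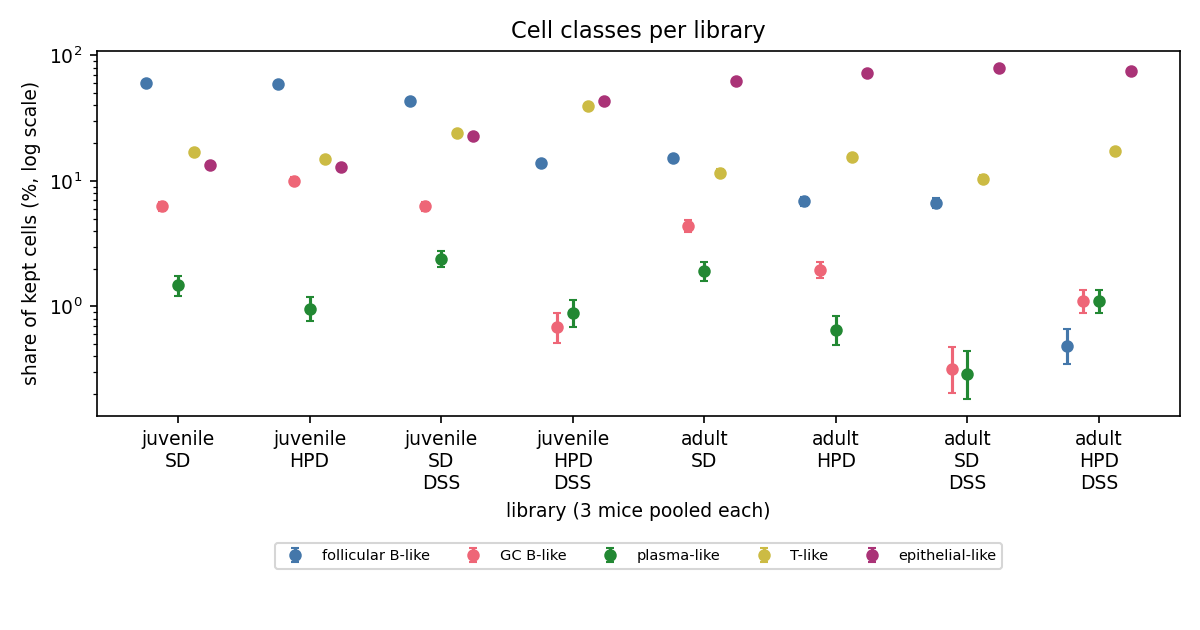
Shares of cells per library. Follicular B-like cells ran from 60.2% in juvenile SD to 0.486% in adult HPD DSS, while epithelial-like droplets ran from 13% in juvenile HPD to 79.6% in adult SD DSS.

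The share of follicular B-like cells was lower in the adult library of all 4 age pairs, 44.4 ± 21.7% to 7.34 ± 6.08% on average (mean log2 ratio −3.16, SD 1.22). GC B-like cells were lower in 3 of 4 pairs (5.82 ± 3.85% to 1.93 ± 1.75%, −1.62, SD 2.18), T-like cells in 3 (24.0 ± 11.1% to 13.7 ± 3.25%, −0.73, SD 0.60) and plasma-like cells in 2 (1.43 ± 0.700% to 0.991 ± 0.700%, −0.72, SD 1.61). By the exact sign-flip test over the 4 pairs, p = 0.13 for follicular B-like, 0.375 for GC B-like, 0.25 for T-like and 0.625 for plasma-like cells, and 0.13 is the smallest p that 4 pairs can give. None passed after adjustment over 12 tests (lowest adjusted p = 0.375). edgeR on the numbers of cells called fewer follicular B-like (−3.06, adjusted p = 0.00863) and more epithelial-like (1.80, adjusted p = 0.0375) and unnamed cells (2.78, adjusted p = 0.0375) in adults. It did not call GC B-like (−1.73, adjusted p = 0.0664), T-like (−0.74, adjusted p = 0.240) or plasma-like cells (−0.46, adjusted p = 0.513). Counted among cells outside epithelial-like and unnamed clusters, the follicular share was lower in all 4 pairs (−1.58), GC B-like cells gave −0.044, and the T-like share was higher in all 4 (0.85, exact p = 0.13). As a share of B-lineage cells, follicular B-like cells gave only −0.68 (exact p = 0.25), and GC B-like cells turned to 0.86 (exact p = 0.500). Plasma-like cells turned sign by both denominators, to 0.86 (exact p = 0.25) among cells outside epithelial-like and unnamed clusters. With 1 library left out, the lowest and highest values that moved by over 1.5 times were GC B-like −0.73 without juvenile SD DSS or adult SD DSS, plasma-like −1.09 without juvenile SD or adult SD and 0.049 without juvenile SD DSS or adult SD DSS.

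With the high-protein diet the follicular B-like share was lower in all 4 diet pairs (31.5 ± 24.8% to 20.3 ± 26.9%, −1.65, SD 1.58, exact p = 0.13). GC B-like cells were lower in 2 of 4 pairs (−0.47, SD 2.19, exact p = 0.75), plasma-like cells in 3 (−0.42, SD 1.62, exact p = 0.625), and T-like cells were higher in 3 (0.42, SD 0.43, exact p = 0.25). edgeR on the numbers of cells did not call follicular B-like (−1.56, adjusted p = 0.227), GC B-like (−0.55, adjusted p = 0.677), T-like (0.45, adjusted p = 0.677) or plasma-like cells (−0.68, adjusted p = 0.677). As a share of B-lineage cells, follicular B-like cells gave −0.57 (exact p = 0.75) and GC B-like cells 0.61 (exact p = 0.625), and plasma-like cells turned sign. The lowest and highest with 1 library left out, where moved by over 1.5 times, were follicular B-like −0.94 without adult SD DSS or adult HPD DSS, GC B-like −1.23 without adult SD DSS or adult HPD DSS and 0.44 without juvenile SD DSS or juvenile HPD DSS, plasma-like −1.20 without adult SD DSS or adult HPD DSS and −0.043 without adult SD or adult HPD.

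With DSS both B-like classes were lower in all 4 pairs: follicular B-like cells 35.5 ± 28.4% to 16.2 ± 19.2% (−1.89, SD 1.45) and GC B-like cells 5.66 ± 3.41% to 2.09 ± 2.81% (−2.13, SD 2.00), each with exact p = 0.13 and adjusted p = 0.375. Plasma-like cells were lower in 2 of 4 pairs (−0.34, SD 1.64, exact p = 0.875) and T-like cells higher in 3 (0.47, SD 0.67, exact p = 0.375). edgeR on the numbers of cells did not call follicular B-like (−1.80, adjusted p = 0.117), GC B-like (−1.72, adjusted p = 0.130), T-like (0.46, adjusted p = 0.621) or plasma-like cells (−0.085, adjusted p = 0.903). It called neutrophil-like cells with diet (adjusted p = 0.0487) and DSS (adjusted p = 0.0415), which numbered 0, 0, 0, 19, 0, 0, 0 and 5. Among cells outside epithelial-like and unnamed clusters the T-like share was higher in all 4 DSS pairs (0.94, exact p = 0.13). As a share of B-lineage cells, follicular B-like cells gave only −0.41 (exact p = 0.875) and GC B-like cells −0.64 (exact p = 0.500). Plasma-like cells turned sign by both denominators. Among values with 1 library left out, the lowest and highest moved by over 1.5 times were follicular B-like −1.25 without adult HPD or adult HPD DSS, T-like 0.16 without juvenile HPD or juvenile HPD DSS, plasma-like −0.71 without adult HPD or adult HPD DSS and 0.45 without adult SD or adult SD DSS. Shares of a whole are tied to each other, so more epithelial-like droplets in a library lower every other share.

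In follicular B-like cells of adult mice, 7 of 22 genes of the dissociation and immediate early list fell, with 3 of 14 chemokine receptor and homing genes. Nr4a1, a nuclear receptor induced by antigen receptor signaling, fell by 1.85 ± 0.24 (adjusted p = 0.00344, from 463 ± 226 to 114 ± 22 CPM). The AP-1 gene Junb fell by 1.55 ± 0.15 (adjusted p = 0.000472, from 1488 ± 207 to 499.6 ± 122 CPM), and Myc fell by 1.47 ± 0.21 (adjusted p = 0.00719, from 267 ± 81.8 to 85.7 ± 27.9 CPM). Further genes that fell were Ier2 (−1.21 ± 0.16, adjusted p = 0.00516), Dusp1 (−1.14 ± 0.17, adjusted p = 0.0102), Ppp1r15a (−1.06 ± 0.20, adjusted p = 0.0443) and the activation marker Cd83 (−0.87 ± 0.16, adjusted p = 0.0327). Among receptors that place B cells in lymphoid tissue, Ccr7 fell by 1.69 ± 0.19 (adjusted p = 0.00117, from 570.2 ± 85.4 to 161 ± 45.4 CPM), and Cxcr5 (−0.95 ± 0.19, adjusted p = 0.0464) and Gpr183 (−0.99 ± 0.17, adjusted p = 0.0236) fell too. The summed CPM of the dissociation and immediate early list was lower in every adult library than in any juvenile one in 4 classes (ranges are juvenile against adult): 7786 to 9880.4 against 3869 to 4699 in follicular B-like, 6184 to 8146 against 2145 to 3667 in T-like, 4003 to 6315 against 2947 to 3127 in plasma-like and 10890.2 to 12297 against 3922 to 8577 in macrophage or monocyte-like cells. In GC B-like cells the ranges met (2460.0 to 3026 against 1456 to 2499.7). Heat shock genes summed to 4945 to 9092 against 3681 to 4611 in follicular B-like, 4742 to 8582 against 3448 to 4089 in T-like and 6587 to 12240.4 against 3789.8 to 4382 in macrophage or monocyte-like cells. Their ranges met in GC B-like (8232 to 11098 against 6093 to 10049) and plasma-like cells (2769.6 to 6052 against 1319 to 3742). Median mitochondrial UMIs per barcode were 2.40% to 3.23% in juvenile and 3.19% to 5.39% in adult libraries, and no value here sets tissue handling apart from age.

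In all, 60 of 9488 genes changed with age in this class, 38 higher and 22 lower in adults (edgeR). In the dissociation and immediate early list 7 of 22 genes fell and 15 did not pass (15 fell when adjusted over the list alone), with a median of −0.88 and camera adjusted p = 8.58e-22 (0.0734 with an estimated correlation). In the heat shock list 0 of 15 genes passed (12 fell when adjusted over the list alone), with a median of −0.72 and camera adjusted p = 9.41e-11 (0.311 with an estimated correlation). Among chemokine receptors and homing genes 3 of 14 genes fell and 11 did not pass (1 rose and 6 fell when adjusted over the list alone), with a median of −0.44 and camera adjusted p = 8.66e-07 (0.110 with an estimated correlation). In the naive and follicular B list 3 of 21 genes fell and 18 did not pass (4 fell when adjusted over the list alone), with a median of −0.38 and camera adjusted p = 8.66e-07 (0.380 with an estimated correlation). In glycolysis, the pathway in which Pkm acts, 0 of 16 genes passed (0 when adjusted over the list alone), with a median of 0.22 and camera adjusted p = 0.409. Pkm (0.21 ± 0.20, adjusted p = 0.679) did not pass. Of interferon and STAT1 targets 0 of 37 genes passed (0 when adjusted over the list alone), with a median of −0.25 and camera adjusted p = 0.203. The 22 genes that fell also moved within clusters, by a check added after the result was seen: their median was −1.21, −1.14 with the mix of clusters held fixed (22 of 22 below 0) and −0.035 from the mix alone. Response lists were left out of the clustering genes, so for their members a small part from the mix was partly set in advance. Cluster 0 was the largest cluster of the class in juvenile SD, juvenile HPD and juvenile SD DSS (57.8%, 57.4% and 48.4%), and cluster 1 in juvenile HPD DSS and the 4 adult libraries (56.4% to 86.2%). The count was 25 without juvenile SD, 17 without juvenile SD DSS, 26 without adult SD, 14 without adult HPD and 93 without adult HPD DSS. DESeq2 called 191 genes, and a model with age alone 19.

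Of the 38 genes higher in adult follicular B-like cells, 23 had more CPM in epithelial-like droplets than in this class, and 6 were erythroid. Among the named genes with at least 10 CPM that rose in all 4 pairs, the goblet cell genes rose most, Spink4 (3.53 ± 0.41, adjusted p = 0.00136, from 9.41 ± 9.02 to 62.3 ± 24.4 CPM) and Clca1 (3.38 ± 0.61, adjusted p = 0.0286), with Krt19 (2.98 ± 0.32, adjusted p = 0.000950) and Krt8 (1.74 ± 0.34, adjusted p = 0.0452). Spink4 reached 1461 CPM in epithelial-like droplets. In the epithelial list 3 of 20 genes rose and 17 did not pass (11 rose when adjusted over the list alone), with a median of 1.38 and camera adjusted p = 3.70e-15 (0.198 with an estimated correlation). Genes not higher in epithelial-like droplets included the cytotoxic gene Nkg7 (3.10 ± 0.51, adjusted p = 0.0184, from 2.12 ± 1.02 to 31.5 ± 41.1 CPM), Ighg2b (1.91 ± 0.31, adjusted p = 0.0155, from 17.3 ± 4.39 to 85.0 ± 57.7 CPM) and Myo1f (1.86 ± 0.37, adjusted p = 0.0464). Nkg7 is also among the leading genes of T-like clusters 2 and 6, and a source in T-like cells was not tested. The epithelial-like share itself was 13% to 43.3% in juvenile and 62.9% to 79.6% in adult libraries.

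**Figure D2:**
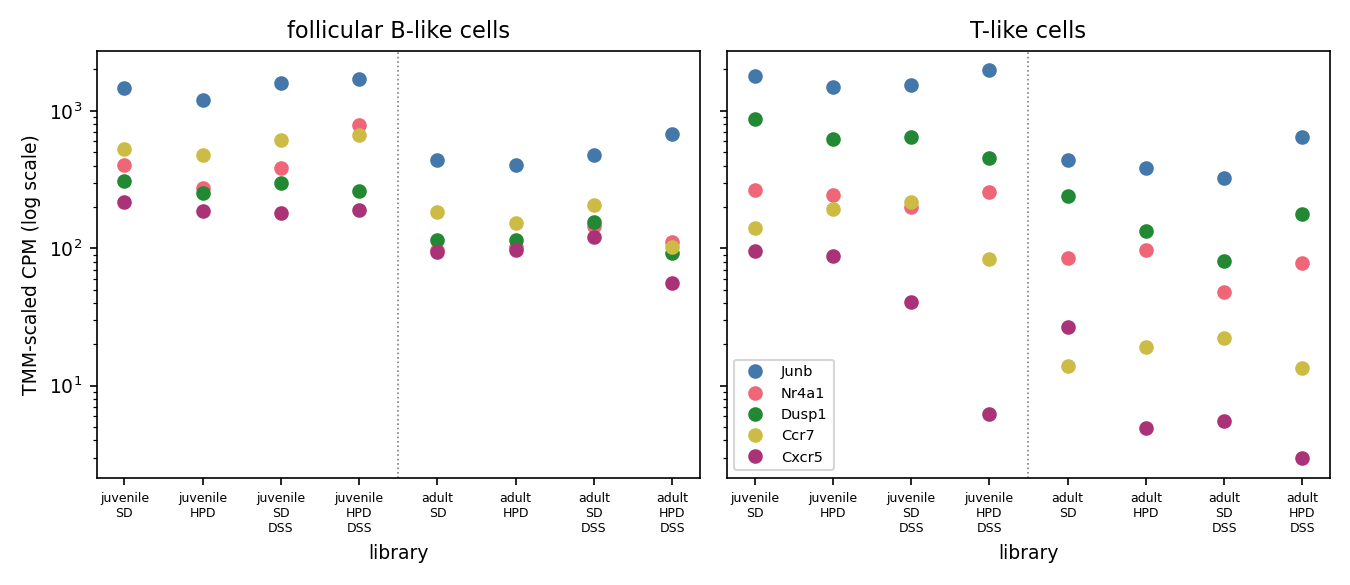
Genes that changed with age in follicular B-like cells, per library. Junb went from 1488 ± 207 to 499.6 ± 122 CPM and Ccr7 from 570.2 ± 85.4 to 161 ± 45.4 CPM (mean ± SD, n = 4 and 4).

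Neither gene of the series title passed with diet in follicular B-like cells: Stat1 (−0.67 ± 0.35, adjusted p = 1.00, from 295 ± 111 to 179 ± 64.5 CPM) and Pkm (0.052 ± 0.20, adjusted p = 1.00, from 237 ± 32.4 to 268 ± 101 CPM). Apart from erythroid genes, the list with the largest median was that of interferon and STAT1 targets, where 0 of 37 genes passed (0 when adjusted over the list alone), with a median of −0.99 and camera adjusted p = 2.44e-16 (0.538 with an estimated correlation). No gene of that list had a fold change above 0. In MHC class I presentation 0 of 18 genes passed (0 when adjusted over the list alone), with a median of −0.37 and camera adjusted p = 8.68e-14 (0.398 with an estimated correlation). In cholesterol synthesis 0 of 22 genes passed (0 when adjusted over the list alone), with a median of −0.36 and camera adjusted p = 1.40e-06 (0.398 with an estimated correlation). In glycolysis 0 of 16 genes passed (0 when adjusted over the list alone), with a median of 0.075 and camera adjusted p = 0.718, and among epithelial genes 0 of 20 genes passed (10 rose when adjusted over the list alone), with a median of 0.90 and camera adjusted p = 5.58e-16 (0.398 with an estimated correlation). Among single genes 5 of 9488 rose and none fell: the intestinal peptide gene Guca2b (2.23 ± 0.32, adjusted p = 0.0276, from 12.5 ± 9.55 to 90.3 ± 88.4 CPM), which is higher in epithelial-like droplets, and the erythroid genes Hbb-bs, Hba-a1, Hba-a2 and Alas2, whose counts are given with DSS below. The count was 14 without juvenile SD, 47 without juvenile HPD, 71 without adult SD, 0 without adult SD DSS and 0 without adult HPD DSS, and without droplets holding hemoglobin it was 0.

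The interferon difference was not the same in each diet pair. Summed over the list, follicular B-like cells held 8367, 4057, 7777, 2344, 1941, 4441, 7277 and 2217 CPM. Counting genes with at least 20 UMIs, a minimum chosen after the values were seen, the median log2 ratio of HPD over SD was −1.27 in juvenile mice without DSS (40 of 40 genes lower) and −1.80 with DSS (35 of 38). It was 1.33 in adults without DSS (3 of 35 lower) and −1.56 with DSS (31 of 33). With the minimum of 200 UMIs set before, the adult pair without DSS gave 0.85 over 6 genes. T-like cells moved the same way in the same libraries (−1.44, −1.17, 0.52 and −1.85 in that order), and macrophage or monocyte-like cells gave −2.13, −1.85, −0.062 and −2.16. A cluster led by Ifit3b, Ms4a4c and Ifit3 (cluster 22) held 12.6% of follicular B-like cells in juvenile SD and at most 2.08% in any other library. Each pair compares those 2 libraries, so no test was made.

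**Figure D3:**
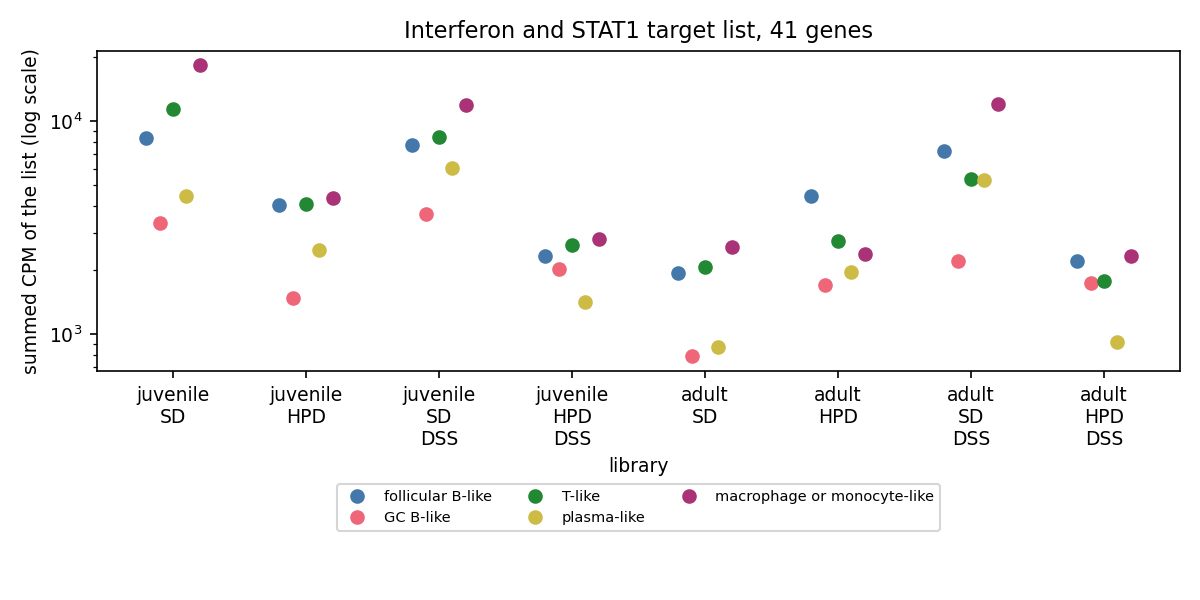
Summed CPM of interferon and STAT1 targets per library and class. In follicular B-like cells the sum was 8367 in juvenile SD, 4057 in juvenile HPD, 1941 in adult SD and 4441 in adult HPD.

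With DSS, 9 of 9488 genes rose in follicular B-like cells and none fell (edgeR). Of these, 4 are enterocyte or enteroendocrine genes: Pyy (4.28 ± 0.34, adjusted p = 5.63e-05, from 1.68 ± 0.560 to 24.3 ± 11.7 CPM), Rbp2 (3.48 ± 0.50, adjusted p = 0.0139), Guca2b (2.51 ± 0.33, adjusted p = 0.00658) and Apoa4 (6.09 ± 0.67, adjusted p = 0.00129), the last higher in 3 of 4 pairs. The other 5 are erythroid (Hba-a1, Hba-a2, Hbb-bs, Hbb-bt and Alas2). Follicular B-like droplets held 4407 hemoglobin UMIs in adult HPD DSS, 472 in adult SD DSS and 78 in juvenile HPD DSS, against at most 5 in any other library. T-like droplets held 9245, 99 and 1717 in the same libraries and 0 in the rest.

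Genes of the B cell itself did not pass with DSS: Stat1 (−0.028 ± 0.34, adjusted p = 1.00, from 233 ± 81.1 to 241 ± 137 CPM) and Pkm (0.17 ± 0.20, adjusted p = 1.00, from 229.8 ± 33.1 to 275 ± 97.4 CPM). Of interferon targets 0 of 37 genes passed (0 when adjusted over the list alone), with a median of −0.15 and camera adjusted p = 0.671. In glycolysis 0 of 16 genes passed (0 when adjusted over the list alone), with a median of 0.13 and camera adjusted p = 0.279. Among epithelial genes 2 of 20 genes rose and 18 did not pass (9 rose when adjusted over the list alone), with a median of 1.02 and camera adjusted p = 8.36e-14 (0.615 with an estimated correlation), and among naive and follicular B genes 0 of 21 genes passed (0 when adjusted over the list alone), with a median of −0.17 and camera adjusted p = 0.0214 (0.883 with an estimated correlation). In all, 578 genes had an unadjusted p < 0.05, DESeq2 called 8, and the count was 29 without juvenile SD, 24 without adult SD and 5 without adult HPD DSS. Without droplets holding hemoglobin it was 4. Camera called 10 lists, and 5 without juvenile HPD, 6 without adult HPD and 5 without adult HPD DSS. It called far fewer with an estimated correlation, and fry called none.

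In GC B-like cells the genes higher in adults were mostly epithelial ones. Lgals2 (3.31 ± 0.41, adjusted p = 0.00691, from 3.21 ± 0.973 to 33.5 ± 17.7 CPM), Lgals4 (2.42 ± 0.20, adjusted p = 0.000166), Krt19 (2.90 ± 0.43, adjusted p = 0.0139) and Krt8 (2.32 ± 0.30, adjusted p = 0.00802) rose, 7 of the 8 genes that rose had more CPM in epithelial-like droplets, and in the epithelial list 3 of 18 genes rose and 15 did not pass (15 rose when adjusted over the list alone), with a median of 1.89 and camera adjusted p = 4.77e-30 (0.284 with an estimated correlation). The 6 genes that fell were all immunoglobulin variable genes, which differ between clones. Among GC dark zone genes 0 of 15 genes passed (1 fell when adjusted over the list alone), with a median of −0.28 and camera adjusted p = 5.66e-05 (0.408 with an estimated correlation), and among cell cycle genes 0 of 41 genes passed (0 when adjusted over the list alone), with a median of −0.19 and camera adjusted p = 0.000382 (0.583 with an estimated correlation). Among heat shock genes 0 of 15 genes passed (5 fell when adjusted over the list alone), with a median of −0.62 and camera adjusted p = 8.64e-08 (0.478 with an estimated correlation). Among dissociation and immediate early genes 0 of 21 genes passed (2 fell when adjusted over the list alone), with a median of −0.56 and camera adjusted p = 6.91e-07 (0.408 with an estimated correlation). Of interferon targets 0 of 30 genes passed (0 when adjusted over the list alone), with a median of −0.83 and camera adjusted p = 0.000382 (0.666 with an estimated correlation), while in glycolysis 0 of 16 genes passed (0 when adjusted over the list alone), with a median of 0.0091 and camera adjusted p = 0.642. Neither Stat1 (−0.79 ± 0.23, adjusted p = 0.317) nor Pkm (−0.0077 ± 0.20, adjusted p = 1.00) passed. In all, 14 of 8952 genes changed (edgeR), and the count was 22 without juvenile SD, 8 without juvenile HPD, 25 without juvenile HPD DSS, 3 without adult SD, 23 without adult HPD and 38 without adult HPD DSS. DESeq2 called 31, and classes set by marker scores gave 0. With predicted doublets kept, none of Lgals2, Lgals4, Krt19 and Krt8 passed. Camera called 13 lists, and 7 without juvenile SD and 7 without adult SD, but none with an estimated correlation, and fry called none.

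With the high-protein diet, cholesterol synthesis genes had the lowest camera p in GC B-like cells: 0 of 25 genes passed (0 when adjusted over the list alone), with a median of −0.35 and camera adjusted p = 7.67e-12 (0.449 with an estimated correlation). Among MYC and nucleolar genes 0 of 28 genes passed (0 when adjusted over the list alone), with a median of −0.23 and camera adjusted p = 1.33e-09 (0.449 with an estimated correlation). In glycolysis 0 of 16 genes passed (0 when adjusted over the list alone), with a median of −0.091 and camera adjusted p = 0.0225 (0.449 with an estimated correlation). Of interferon targets 0 of 30 genes passed (0 when adjusted over the list alone), with a median of −0.58 and camera adjusted p = 0.000445 (0.795 with an estimated correlation). Neither Pkm (−0.31 ± 0.20, adjusted p = 1.00, from 613 ± 126 to 476 ± 119 CPM) nor Stat1 (−0.47 ± 0.22, adjusted p = 1.00, from 157 ± 61.7 to 105 ± 33.3 CPM) passed. Of 14 genes that changed (edgeR, 5 higher and 9 lower), 12 were immunoglobulin genes, and the other two were Hbb-bs and the mast cell protease gene Mcpt1, named after its value was seen. The count was 7 without juvenile HPD, 4 without juvenile SD DSS and 26 without adult HPD DSS. DESeq2 called 5, and classes set by marker scores gave 0. Camera called 11 lists, and 6 without juvenile HPD DSS, 7 without adult SD DSS and 7 without adult HPD DSS. It called none with an estimated correlation, and fry called none.

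With DSS only the immunoglobulin genes Ighv1-50 and Ighv13-2 passed in GC B-like cells, both lower (edgeR, 2 of 8952, with 458 at an unadjusted p < 0.05 and 4 called by DESeq2). Of interferon targets 0 of 30 genes passed (0 when adjusted over the list alone), with a median of 0.21 and camera adjusted p = 0.00786 (0.858 with an estimated correlation). Among epithelial genes 0 of 18 genes passed (7 rose and 2 fell when adjusted over the list alone), with a median of 0.68 and camera adjusted p = 0.000567 (0.858 with an estimated correlation), and in glycolysis 0 of 16 genes passed (0 when adjusted over the list alone), with a median of 0.10 and camera adjusted p = 0.572. Neither Stat1 (0.37 ± 0.22, adjusted p = 1.00) nor Pkm (0.15 ± 0.20, adjusted p = 1.00) passed. The 2 immunoglobulin genes were named after their values were seen. The count was 16 without juvenile SD, 6 without juvenile HPD, 9 without juvenile HPD DSS, 4 without adult SD, 8 without adult HPD, 0 without adult SD DSS and 7 without adult HPD DSS. Camera called 11 lists, and 4 without juvenile HPD and 6 without juvenile SD DSS, but none with an estimated correlation, and fry called none. The class had 24 cells in adult SD DSS and 53 in juvenile HPD DSS.

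The IgA share of GC B-like cells stood apart in adult SD. IgA made up 40.2%, 32.1%, 38.6%, 23.5%, 78.5%, 27.5%, 21.6% and 27.1% of heavy-chain constant-region UMIs. T-like droplets, which make no antibody, gave 4.36%, 3.44%, 5.98%, 14.0%, 23.4%, 26.2%, 4.55% and 48.6% of the few such UMIs they held. Median depth was 7231 UMIs in GC B-like against 2782 in T-like cells of juvenile SD, and 4334 against 1604 in adult SD. The IgA share was lower with DSS in all 4 pairs (mean difference −16.9 points, SD 27.0, exact p = 0.13, adjusted p = 0.375). With the high-protein diet it was lower in 3 of 4 (mean difference −17.2 points, SD 24.2, exact p = 0.25). Of the 4 pairs adult SD and adult HPD differed most, and an exchange of their labels, left open below, would leave the share lower in 2 of 4 and turn the sign of the mean. Between ages it was higher in 2 of 4 (mean difference 5.10, SD 23.7, exact p = 0.875). With adult SD or its partner left out these differences were −3.50 points with DSS, −5.88 with diet and −5.99 between ages, where the sign turned. With predicted doublets kept they were −3.88, −8.17 and −7.37. The direction with DSS then turned in juvenile SD (40.1% to 47.9%), juvenile HPD (33.1% to 65.5%) and adult HPD (27.9% to 29.1%). Only adult SD still fell with DSS in that setting (78.6% to 21.6%). The fall in all 4 pairs therefore depends on the removal of doublets. The age difference was 8.33 without adult HPD or juvenile HPD and 12.5 without adult SD DSS or juvenile SD DSS. In plasma-like cells the IgA share was 51.5%, 37.0%, 69.7%, 77.5%, 89.2%, 82.3%, 80.4% and 78.6%.

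**Figure D4:**
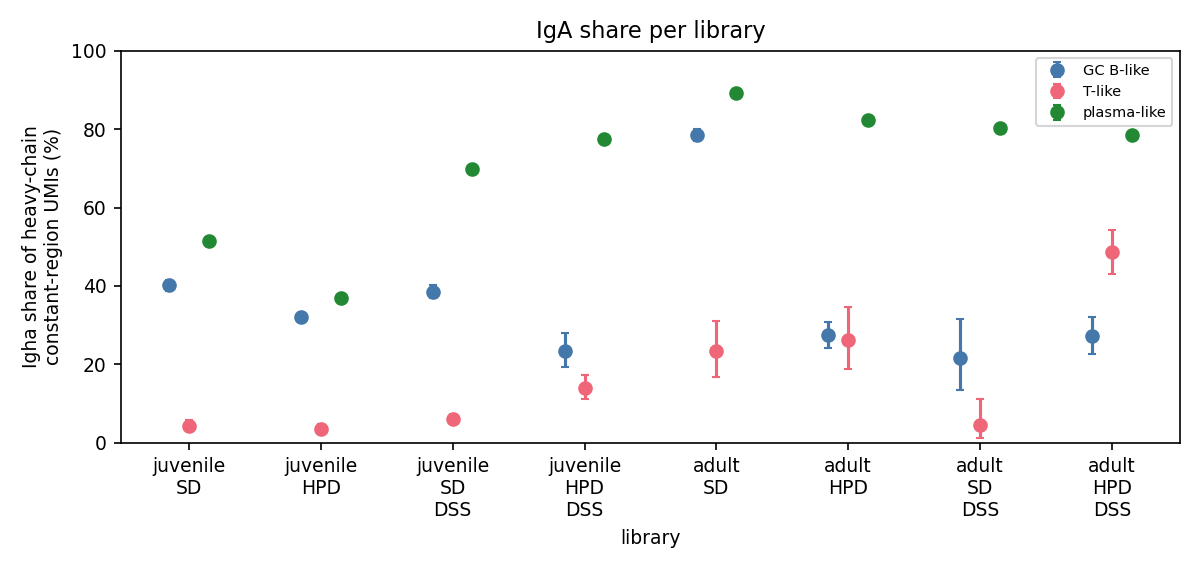
IgA share of heavy-chain constant-region UMIs in GC B-like and T-like cells per library. GC B-like cells of adult SD gave 78.5%, and the other 7 libraries 21.6% to 40.2%.

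T-like cells differed most with age, with 374 of 11420 genes changed, 118 higher and 256 lower in adults (edgeR). Genes of naive T cells fell: Ccr7 fell by 3.23 ± 0.34 (adjusted p = 0.00481, from 158 ± 59.7 to 17.2 ± 4.24 CPM), the transcription factor Lef1 (−2.21 ± 0.28, adjusted p = 0.00781), S1pr1 (−2.37 ± 0.34, adjusted p = 0.0108), Klf2 (−2.31 ± 0.26, adjusted p = 0.00732, from 382 ± 156 to 79.8 ± 28.7 CPM), Igfbp4 (−2.72 ± 0.53, adjusted p = 0.0312) and Dapl1 (−2.67 ± 0.43, adjusted p = 0.0168). Genes of T follicular helper cells, which help B cells in the follicle, fell as well: Izumo1r fell by 2.81 ± 0.38 (adjusted p = 0.00920, from 239 ± 163 to 42.1 ± 48.4 CPM), Cxcr5 (−2.66 ± 0.46, adjusted p = 0.0192), Icos (−2.12 ± 0.27, adjusted p = 0.00781), Slamf6 (−1.94 ± 0.26, adjusted p = 0.00826), Sh2d1a (−1.80 ± 0.26, adjusted p = 0.0113) and Bcl6 (−1.39 ± 0.27, adjusted p = 0.0312). Junb fell by 1.96 ± 0.20 (adjusted p = 0.00374, from 1700.0 ± 233 to 448 ± 140.2 CPM) and Hspa8 fell by 1.23 ± 0.16 (adjusted p = 0.00781, from 1884 ± 456 to 795 ± 20.9 CPM). Of 24 cholesterol synthesis genes 3 rose, Dhcr24 (1.14 ± 0.18, adjusted p = 0.0154), Lss (1.20 ± 0.26, adjusted p = 0.0418) and Srebf2 (0.69 ± 0.15, adjusted p = 0.0430), all with more CPM in epithelial-like droplets than in T-like cells. Among named genes that rose in all 4 pairs the enkephalin gene Penk (3.39 ± 0.68, adjusted p = 0.0340) rose most.

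Among naive T genes 10 of 12 genes fell and 2 did not pass (12 fell when adjusted over the list alone), with a median of −2.21 and camera adjusted p = 1.98e-27 (0.0923 with an estimated correlation). In the T follicular helper list 10 of 16 genes fell and 6 did not pass (14 fell when adjusted over the list alone), with a median of −1.67 and camera adjusted p = 1.36e-19 (0.115 with an estimated correlation). In the dissociation and immediate early list 12 of 22 genes fell and 10 did not pass (18 fell when adjusted over the list alone), with a median of −1.14 and camera adjusted p = 1.98e-27 (0.0801 with an estimated correlation), and in heat shock 9 of 16 genes fell and 7 did not pass (15 fell when adjusted over the list alone), with a median of −0.77 and camera adjusted p = 1.67e-17 (0.115 with an estimated correlation). Among chemokine receptors and homing genes 7 of 17 genes fell and 10 did not pass (1 rose and 11 fell when adjusted over the list alone), with a median of −0.77 and camera adjusted p = 4.96e-15 (0.0892 with an estimated correlation). In cholesterol synthesis 3 of 24 genes rose and 21 did not pass (9 rose when adjusted over the list alone), with a median of 0.49 and camera adjusted p = 3.79e-07 (0.338 with an estimated correlation). Of interferon targets 3 of 41 genes fell and 38 did not pass (5 fell when adjusted over the list alone), with a median of −0.79 and camera adjusted p = 9.80e-10 (0.436 with an estimated correlation), while in glycolysis 0 of 18 genes passed (0 when adjusted over the list alone), with a median of −0.20 and camera adjusted p = 0.424. Among epithelial genes 6 of 20 genes rose and 14 did not pass (13 rose when adjusted over the list alone), with a median of 1.63 and camera adjusted p = 4.96e-15 (0.115 with an estimated correlation), and 71 of the 118 genes that rose had more CPM in epithelial-like droplets. The count was 228 without juvenile SD, 96 without juvenile HPD, 129 without juvenile SD DSS, 938 without juvenile HPD DSS, 89 without adult SD, 97 without adult HPD and 88 without adult SD DSS. DESeq2 called 715.

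The clusters that make up the T-like class differed between libraries. A cluster marked by Izumo1r, Icos and Tcf7 (cluster 16) was 35.1%, 31.7% and 17.2% of T-like cells in juvenile SD, juvenile HPD and juvenile SD DSS, 1.46% in juvenile HPD DSS, and 0.794% to 10.0% in adults. A cluster marked by Igfbp4, Lef1 and Dapl1 (cluster 13) was 12.5% to 29.8% in juvenile and 1.44% to 5.84% in adult libraries. A cluster marked by Gzmk, Cd8b1 and Ccl5 (cluster 6) was 11.6% to 27.1% in juvenile libraries and 36.9%, 58.3% and 55.3% in adult SD, adult HPD and adult SD DSS. Adult HPD DSS differed from these, with 15.1% in cluster 6 and 74.0% in a cluster marked by Cd7, Fcer1g and Gzma (cluster 2).

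**Figure D5:**
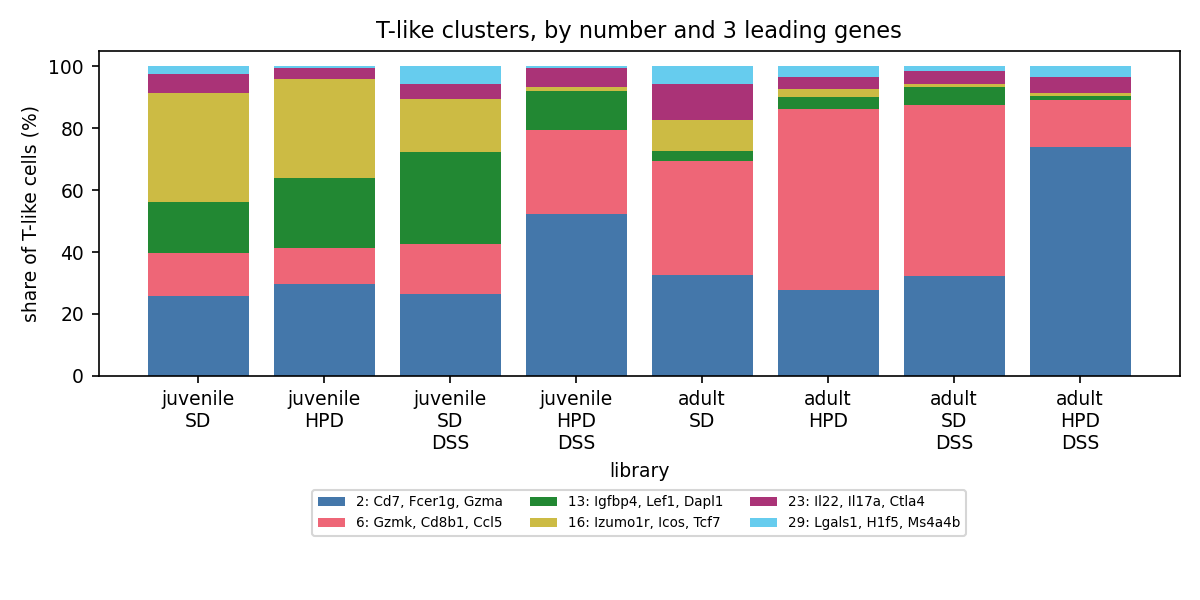
Clusters within the T-like class per library. The cluster marked by Izumo1r, Icos and Tcf7 ran from 35.1% in juvenile SD to 0.794% in adult HPD DSS.

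With diet, 1 of 11420 genes passed in T-like cells, Hbb-bt (edgeR, with 1045 at an unadjusted p < 0.05 and 67 called by DESeq2). Neither Stat1 (−1.02 ± 0.30, adjusted p = 0.365, from 579 ± 200.2 to 294 ± 98.2 CPM) nor Pkm (−0.40 ± 0.15, adjusted p = 0.444, from 425 ± 92.1 to 322 ± 18.8 CPM) passed. Of interferon targets 0 of 41 genes passed (35 fell when adjusted over the list alone), with a median of −1.16 and camera adjusted p = 2.63e-29 (0.413 with an estimated correlation). In the cell cycle list 0 of 41 genes passed (24 fell when adjusted over the list alone), with a median of −1.14 and camera adjusted p = 3.55e-26 (0.413 with an estimated correlation). Among T follicular helper genes 0 of 16 genes passed (12 fell when adjusted over the list alone), with a median of −0.94 and camera adjusted p = 1.40e-17 (0.329 with an estimated correlation). In glycolysis 0 of 18 genes passed (0 when adjusted over the list alone), with a median of −0.18 and camera adjusted p = 0.0101 (0.457 with an estimated correlation), and among epithelial genes 0 of 20 genes passed (12 rose when adjusted over the list alone), with a median of 1.11 and camera adjusted p = 5.16e-21 (0.329 with an estimated correlation). The count was 22 without juvenile SD, 44 without juvenile HPD, 0 without juvenile SD DSS, 3 without juvenile HPD DSS, 80 without adult SD, 0 without adult SD DSS and 0 without adult HPD DSS.

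With DSS, 3 of 16 T follicular helper genes fell in T-like cells. Tox2 fell by 1.78 ± 0.19 (adjusted p = 0.00900, from 79.4 ± 31.6 to 23.7 ± 13.2 CPM), Izumo1r fell by 2.30 ± 0.38 (adjusted p = 0.0484, from 220.2 ± 175 to 61.0 ± 84.7 CPM), and Cd40lg (−1.66 ± 0.26, adjusted p = 0.0360) fell. Outside that list, the transcription factor gene Irf4 (−1.23 ± 0.20, adjusted p = 0.0418) fell. In the T follicular helper list 3 of 16 genes fell and 13 did not pass (15 fell when adjusted over the list alone), with a median of −1.57 and camera adjusted p = 1.41e-32 (0.157 with an estimated correlation). Among genes that rose were the ectonucleotidase gene Entpd1 (1.36 ± 0.20, adjusted p = 0.0325), Serpinb9 (1.10 ± 0.15, adjusted p = 0.0266) and S100a4 (2.03 ± 0.32, adjusted p = 0.0381), and the enteroendocrine genes Pyy (4.05 ± 0.37, adjusted p = 0.00593) and Sct (2.62 ± 0.43, adjusted p = 0.0475). Of the 19 genes that rose, 8 had more CPM in epithelial-like droplets and 5 were erythroid, and 20 fell. Hspa1a, a heat shock gene, was among those that fell. With genes higher in epithelial-like cells left out, the heat shock list was lower too (camera adjusted p = 6.23e-05). No list passed with an estimated correlation. Among epithelial genes 2 of 20 genes rose and 18 did not pass (6 rose when adjusted over the list alone), with a median of 0.91 and camera adjusted p = 7.25e-11 (0.313 with an estimated correlation), and in glycolysis 0 of 18 genes passed (0 when adjusted over the list alone), with a median of 0.085 and camera adjusted p = 0.544. In all, 39 of 11420 genes changed (edgeR), and the count was 8 without juvenile HPD, 16 without juvenile SD DSS, 8 without juvenile HPD DSS, 24 without adult SD, 7 without adult HPD, 13 without adult SD DSS and 9 without adult HPD DSS. DESeq2 called 120, a model with DSS alone 0, and classes set by marker scores 5.

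Each interaction was added by itself to the model of the 3 factors, and its value is the difference between 2 log2 fold changes. In simulated data 21 of 85 genes called for diet by DSS in follicular B-like cells were false, more than an adjusted p under 0.05 allows. In follicular B-like cells 2 genes had a diet by DSS interaction (edgeR, and 9 by DESeq2), Igha (3.40 ± 0.41, adjusted p = 0.0192) and the acute phase gene Saa1 (6.56 ± 0.85, adjusted p = 0.0192). Saa1 was at 181 and 74.2 CPM in juvenile and adult HPD DSS and at most 10.9 elsewhere. Epithelial-like cluster 8, 95.4% from juvenile HPD DSS, held 7378 CPM of Saa1. The IgA share in juvenile and adult HPD DSS was 21.5% and 45.9% in follicular B-like droplets, against 2.28% to 8.71% elsewhere. In T-like droplets it was 14.0% and 48.6%, against 3.44% to 26.2% elsewhere. RNA carried over from other cells is therefore left open for these genes. They were named after their values were seen. Age by diet gave 0 genes (edgeR, with 318 at an unadjusted p < 0.05 and 2 by DESeq2), and age by DSS 0 (294 at an unadjusted p < 0.05 and 0 by DESeq2). The diet by DSS count was 82 without juvenile SD, 9 without juvenile HPD, 1 without juvenile SD DSS, 40 without juvenile HPD DSS, 17 without adult SD, 32 without adult HPD, 1 without adult SD DSS and 5 without adult HPD DSS. Age by diet gave 16 without juvenile HPD, 2 without juvenile SD DSS, 49 without juvenile HPD DSS, 10 without adult SD, 15 without adult HPD and 57 without adult SD DSS. Age by DSS gave 14 without juvenile SD, 1 without juvenile HPD, 5 without adult SD, 58 without adult HPD and 1 without adult SD DSS.

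In GC B-like cells 18 genes had an age by diet interaction (edgeR, and 13 by DESeq2), 17 of them above 0. They include the interferon targets Rtp4, Usp18 (7.93 ± 1.28, adjusted p = 0.0158) and Slfn2 (3.00 ± 0.52, adjusted p = 0.0222). Slfn2 was at 79.1 CPM in juvenile SD, 44.6 in juvenile HPD, 16.4 in adult SD and 66.3 in adult HPD. Rtp4 (adjusted p = 0.0128) had 0 UMIs in 3 libraries. The epithelial genes Apoa1, Fabp2, Krt20 and Muc2 and 11 immunoglobulin genes make up the rest. Diet by DSS gave 4 genes (DESeq2 4), Fabp6 (−4.71 ± 0.68, adjusted p = 0.0402) and the immunoglobulin genes Igkv3-7, Ighv1-85 and Igkv1-99, and age by DSS 0 (edgeR, with 324 at an unadjusted p < 0.05 and 1 by DESeq2). These genes were named after their values were seen. The age by diet count was 42 without juvenile SD DSS, 68 without juvenile HPD DSS, 2 without adult SD, 67 without adult HPD, 36 without adult SD DSS and 75 without adult HPD DSS. Diet by DSS gave 37 without juvenile SD, 15 without juvenile HPD, 0 without juvenile SD DSS, 27 without juvenile HPD DSS, 33 without adult SD, 72 without adult HPD and 36 without adult HPD DSS. Age by DSS gave 15 without juvenile SD, 17 without juvenile HPD, 3 without juvenile HPD DSS, 4 without adult SD, 29 without adult HPD and 1 without adult SD DSS.

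Diet was also compared within single conditions, which compares those libraries and not the diets. Values are log2 ratios with 95% counting intervals, which hold no spread between animals. In follicular B-like cells of juvenile mice without DSS, the interferon genes Ifit3b (−3.53, −3.89 to −3.20), Ifit1bl1 (−3.43, −3.94 to −2.99) and Stat1 (−0.65, −0.73 to −0.57) were lower in HPD, and Pkm (−0.13, −0.21 to −0.044) differed little. The goblet cell gene Muc2 (−4.47, −5.33 to −3.80) was lower and the Paneth cell gene Defa22 (5.07, 4.62 to 5.61) higher. The glycolysis median was 0.090 (−0.050 to 0.15). With DSS, Ifitm3 (−4.16, −5.58 to −3.20), Oasl2 (−2.88, −3.90 to −2.11) and Stat1 (−1.60, −1.82 to −1.39) were lower in juvenile HPD DSS, Saa1 (7.50, 6.40 to 9.27) and Reg3b (4.27, 4.15 to 4.39) higher, and the glycolysis median was −0.066 (−0.17 to 0.038). In adults without DSS, Ifi27l2a (1.47, 1.29 to 1.64), Rnf213 (1.41, 1.07 to 1.75) and Stat1 (0.90, 0.60 to 1.20) were higher in HPD and the cold-inducible gene Cirbp (−1.25, −1.79 to −0.78) lower, and the glycolysis median was −0.14 (−0.38 to −0.028). Adult HPD DSS had 39 cells of this class.

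GC B-like cells of juvenile HPD had fewer interferon transcripts than those of juvenile SD, with Rtp4 (−3.90, −4.68 to −3.27), Usp18 (−3.41, −4.10 to −2.83), Isg15 (−2.54, −2.85 to −2.24) and Stat1 (−0.88, −1.02 to −0.74) and a list median of −1.21 (−1.28 to −1.08). In the juvenile DSS pair the median was −0.59 (−0.96 to −0.29). Pkm (−0.25, −0.33 to −0.17) was lower in the pair without DSS and Pkm (0.31, 0.11 to 0.49) higher in the pair with DSS. In adults without DSS, Igha (−1.90, −2.12 to −1.69) was lower in HPD and Ighm (2.03, 1.75 to 2.31) higher, with Ifi27l2a (2.22, 1.94 to 2.51) higher too and Pkm (−0.43, −0.66 to −0.21) lower. Glycolysis medians were −0.073 (−0.13 to 0.014), −0.12 (−0.28 to −0.0022) and −0.16 (−0.33 to 0.023) in these 3 pairs. In the adult DSS pair, adult SD DSS held 181170.0 CPM of the ribosomal RNA feature Rn18s-rs5, and its values rest on 24 cells.

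Between ages within single conditions, the interferon median of follicular B-like cells was −2.24 (−2.41 to −2.04) in SD, 0.27 (0.12 to 0.39) in HPD and −0.0029 (−0.097 to 0.12) in SD with DSS. Between DSS and none it was −0.41 (−0.48 to −0.32) in juvenile SD, −0.92 (−1.06 to −0.73) in juvenile HPD and 1.57 (1.47 to 1.72) in adult SD. In GC B-like cells it was −1.88 (−2.04 to −1.56) between ages in SD and 0.43 (0.25 to 0.61) between DSS and none in juvenile HPD.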

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

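In this part the tests of hemoglobin and epithelial transcripts, of interferon targets across cell types and at both ages, and of all splits of the libraries were chosen only after the result was seen, while the tests of T-like clusters, of the interferon-led cluster and of free interferon RNA were set before their values were seen.

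Shares were screened for a library far from the other 3 of its factor level by Dixon's ratio of gap to range. Of 30 such groups 4 passed that limit, and chance does so in about 1 in 20 groups. Each condition holds 1 library, so a level also mixes the other 2 factors. GC B-like cells made up 10.0% in juvenile HPD against 0.680% to 1.96% in the other HPD libraries. They made up 6.28% in juvenile SD DSS against 0.318% to 1.10% in the other DSS libraries. T-like cells were 39.6% in juvenile HPD DSS against 15.0% to 17.3% in the other HPD libraries. The IgA share of GC B-like cells was 78.5% in adult SD against 21.6% to 27.5% in the other adult libraries, and this share had been seen before the screen was added.

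Effects also differed between groups by tests of interactions: 2 genes for diet by DSS in follicular B-like cells, 18 for age by diet in GC B-like cells and 4 for diet by DSS in GC B-like cells. For the 2 genes in follicular B-like cells 10 of 32 splits of the libraries gave as many (highest other 22). The 18 genes had 4 of 32 (highest other 21) and the 4 genes 30 of 32 (highest other 21). The interactions with a count of 0 gave 32 of 32 splits each, with highest other counts of 22 (age by diet) and 22 (age by DSS) in follicular B-like and 21 (age by DSS) in GC B-like cells. Chance is not excluded for any of them. Some splits call several times the real count, 22 against 2 and 21 against 4. These are the highest of 32 splits, some of which are the same fit, and the same splits serve every interaction. Whether they reflect a structure of the samples other than the factors was not tested.

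For the main effects, 33 of the 35 splits of the 8 libraries into 4 and 4 could be fitted, since 2 equal another factor. Splits with as many genes as the real one in follicular B-like cells numbered 1 (real 60, highest other 6) for age, 5 (real 5, highest other 80) for diet and 2 (real 9, highest other 64) for DSS. In GC B-like cells they numbered 2 (real 14, highest other 14), 4 (real 14, highest other 24) and 16 (real 2, highest other 41), and in T-like cells 1 (real 374, highest other 1), 7 (real 1, highest other 4) and 1 (real 39, highest other 6). Only the real split gave as many genes for age in follicular B-like and T-like cells and for DSS in T-like cells, and for no other gene count. With 33 splits the share cannot fall below 1 in 33. It was not adjusted over the counts tested, and some splits are the same fit once the other factors are in the model. This falls short of excluding chance. For lists the numbers were 2 (real 17, highest other 17), 11 (real 11, highest other 17) and 15 (real 10, highest other 16) in follicular B-like, 9 (real 13, highest other 18), 14 (real 11, highest other 17) and 8 (real 11, highest other 15) in GC B-like and 1 (real 24, highest other 22), 3 (real 19, highest other 23) and 17 (real 14, highest other 19) in T-like cells. Only for age in T-like cells did no other split give as many lists, by 24 against 22. With an estimated correlation no list was called for it, so chance is not excluded there either. The diet split of follicular B-like cells with 80 genes sets juvenile SD, juvenile SD DSS, adult HPD and adult SD DSS against the rest, which is diet with adult SD and adult HPD exchanged. That count, 64 for DSS in follicular B-like cells and 41 in GC B-like cells are several times the real ones, each as the highest of 33 splits. They may reflect a structure of the samples other than the factors, which was not tested.

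Hemoglobin and enterocyte genes make up part of the genes called in B-like and T-like cells. Hemoglobin lies in few droplets: 98.5% of its UMIs are in droplets with 5 or more, 45 of 31588, as red cells or their debris captured with a cell would give, although the protocol lyses red cells. Epithelial transcripts are spread instead: in the 2 libraries with a median of at least 5 epithelial list UMIs per droplet, the medians of the 3 classes lie within 1.22-fold of each other, as free RNA may give. In juvenile HPD DSS and adult HPD DSS these medians were 8.00 and 11.0 in follicular B-like droplets, against 1.00 in juvenile SD. More bleeding or epithelial damage with DSS and more epithelial cells carried along at dissection could each bring such RNA, and no value here parts them.

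The genes that fell with age in T-like cells may reflect a smaller share of naive and follicular helper T cells among the T-like cells captured, lower expression within clusters, or both. Over 222 of the 256 genes, without those higher in epithelial-like droplets, the mix of clusters alone gave 0.411 of the median log2 fold change, which leaves that explanation open, and the change within clusters gave 0.548. The parts differ by list: the mix gave 0.739 for T follicular helper and 0.709 for naive T genes, but 0.165 for dissociation and immediate early and 0.221 for heat shock genes, which moved within clusters (0.768 and 0.859). This contrast was partly set by the clustering. Heat shock and other response lists were left out of its genes, while T follicular helper and naive T genes lead clusters 16 and 13. For 19 of the 20 genes that fell with DSS the mix gave 0.534 and the change within clusters 0.487, and these cannot be told apart because each lies near 0.5, while the 3 T follicular helper genes among them gave 0.709 from the mix and 0.291 within clusters. Age of the mice, time from dissection to lysis and the larger share of epithelial cells in adult libraries could each lie behind the changes within clusters, and none of these was tested.

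Interferon targets were lower in the juvenile HPD libraries than in their SD partners, and the tests set a local cluster of cells against a response across cell types. Free RNA is excluded, at 1.66% of the list's CPM. As labelled, the adult pair without DSS went the other way (highest median 1.33). With 1 pool per library this cannot exclude a diet effect in all 4 pairs, even if the labels of these 2 libraries are not exchanged. Without the interferon-led cluster the juvenile DSS pair kept −1.76 of −1.80, so that cluster does not carry it there, while the pair without DSS kept 0.654 of its median with 40 of 40 genes lower, where the part of the cluster cannot be told apart from a change in all cells. T-like cells gave a median of −1.17 in the juvenile pair where theirs was nearer 0, so a response across cell types in these libraries is a candidate explanation. Differences between cages or pools of 3 mice, a diet effect that depends on age and DSS, and a diet effect in all 4 pairs with those labels exchanged (though the follicular B-like share fell with HPD in 4 of 4 pairs as labelled, in the adult one without DSS from 15.3% to 6.88%) could each give this, and 1 library per condition cannot part them.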

How the results depend on the processing

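In this part free RNA subtracted, genes higher in epithelial-like cells left out, at least 1500 UMIs per cell, hemoglobin droplets left out, shares outside epithelial-like and unnamed clusters, and the minimum of 20 UMIs were chosen only after the data were seen. Over all alternatives and left-out libraries, 120 of 309 gene counts and 91 of 126 list counts stayed within 1.5 times the reported count, 14 of 180 shares and 4 of 36 IgA differences turned sign (the exact test cannot pass 0.05 with 4 pairs, so their side of the threshold was fixed, and sizes moved more), and 2423 of 3129 values of named genes kept direction and side of the threshold, with 663 no longer past the threshold, 6 newly past it and 37 reversed. Of 576 ratios of single pairs 42 moved beyond their interval and 6 reversed. Counts below are followed by the reported count in parentheses, and the cause was not tested unless given. The alternative scale for single pairs (TMM) moved 1 ratio, that of Rn18s-rs5 between the adult DSS libraries, and reversed none.

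DESeq2 gave genes for age 191 (60), age by diet 2 (0), diet by DSS 9 (2) in follicular B-like cells, age 31 (14), diet 5 (14), DSS 4 (2), age by DSS 1 (0) in GC B-like cells and age 715 (374), diet 67 (1), DSS 120 (39) in T-like cells. With edgeR and RLE factors the model gave genes for diet by DSS 4 (2) in follicular B-like cells. No filter on low counts gave genes for age 531 (60), diet 181 (5), DSS 179 (9), age by diet 72 (0), age by DSS 37 (0), diet by DSS 88 (2) in follicular B-like cells, age 229 (14), diet 146 (14), DSS 165 (2), age by diet 98 (18), age by DSS 52 (0), diet by DSS 92 (4) in GC B-like cells and age 1632 (374), diet 606 (1), DSS 563 (39) in T-like cells. A mean of at least 10 CPM gave genes for age 34 (60) in follicular B-like cells, age 6 (14), age by diet 5 (18), diet by DSS 0 (4) in GC B-like cells and diet 0 (1) in T-like cells. The factor alone in the model gave genes for age 19 (60), diet 0 (5), DSS 1 (9) in follicular B-like cells, age 4 (14), diet 0 (14), DSS 0 (2) in GC B-like cells and age 122 (374), diet 0 (1), DSS 0 (39) in T-like cells.

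Predicted doublets kept gave genes for DSS 16 (9), age by diet 1 (0), diet by DSS 4 (2) in follicular B-like cells, age 7 (14), DSS 19 (2), age by diet 2 (18), diet by DSS 2 (4) in GC B-like cells and diet 4 (1) in T-like cells. A stricter cell filter (1000 UMIs, 5% mitochondrial) gave genes for age 134 (60), diet 0 (5), DSS 5 (9), age by diet 3 (0) in follicular B-like cells, age by DSS 1 (0), diet by DSS 9 (4) in GC B-like cells and diet 2 (1) in T-like cells. At least 1500 UMIs per cell gave genes for age 146 (60), age by diet 3 (0), diet by DSS 0 (2) in follicular B-like cells and age 223 (374), diet 10 (1) in T-like cells. Classes from marker scores gave genes for diet 0 (5), DSS 5 (9), age by diet 2 (0), diet by DSS 1 (2) in follicular B-like cells, age 0 (14), diet 0 (14), DSS 0 (2), age by diet 0 (18), diet by DSS 0 (4) in GC B-like cells and age 211 (374), diet 0 (1), DSS 5 (39) in T-like cells. Its lists were diet 21 (11) in GC B-like cells.

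Immunoglobulin, plasma cell, epithelial and erythroid genes left out gave genes for diet 0 (5), DSS 2 (9) in follicular B-like cells, age 24 (14), diet 3 (14), DSS 6 (2), age by DSS 1 (0), diet by DSS 2 (4) in GC B-like cells and diet 0 (1) in T-like cells. Free RNA subtracted gave genes for age 31 (60), age by diet 1 (0) in follicular B-like cells, age 5 (14), diet 9 (14), DSS 0 (2), age by DSS 1 (0), diet by DSS 8 (4) in GC B-like cells and age 217 (374), diet 0 (1) in T-like cells. Genes higher in epithelial-like cells left out gave genes for diet 0 (5), DSS 1 (9) in follicular B-like cells, age 7 (14), diet 1 (14), DSS 4 (2), age by diet 3 (18), diet by DSS 2 (4) in GC B-like cells and diet 0 (1) in T-like cells. Its lists were age 11 (17), DSS 3 (10) in follicular B-like cells, age 8 (13), diet 4 (11), DSS 3 (11) in GC B-like cells and diet 10 (19) in T-like cells. Hemoglobin droplets left out gave genes for diet 0 (5), DSS 4 (9), diet by DSS 4 (2) in follicular B-like cells and diet 0 (1) in T-like cells.

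An estimated inter-gene correlation gave lists for age 0 (17), diet 0 (11), DSS 1 (10) in follicular B-like cells, age 0 (13), diet 0 (11), DSS 0 (11) in GC B-like cells and age 0 (24), diet 0 (19), DSS 0 (14) in T-like cells. With fry in place of camera there were lists for age 3 (17), diet 0 (11), DSS 0 (10) in follicular B-like cells, age 0 (13), diet 0 (11), DSS 0 (11) in GC B-like cells and age 11 (24), diet 0 (19), DSS 0 (14) in T-like cells.

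Signs turned as follows, with the reported value in parentheses. Pkm with age, GC B-like (−0.0077) was 0.016 with DESeq2, 0.016 with edgeR with RLE factors, 0.013 with a mean of at least 10 CPM, 0.041 with the factor alone in the model, 0.022 with predicted doublets kept, 0.020 with a stricter cell filter (1000 UMIs, 5% mitochondrial), 0.018 with at least 1500 UMIs per cell, 0.0016 with immunoglobulin, plasma cell, epithelial and erythroid genes left out, 0.0011 with free RNA subtracted, 0.032 with genes higher in epithelial-like cells left out and 0.00063 with hemoglobin droplets left out. Pkm with diet, follicular B-like (0.052) was −0.0041 with no filter on low counts and −0.11 with classes from marker scores. Stat1 with DSS, follicular B-like (−0.028) was 0.14 with the factor alone in the model, 0.022 with classes from marker scores and 0.031 with genes higher in epithelial-like cells left out. The IgA share with age, GC B-like (5.10) was −7.37 with predicted doublets kept. With predicted doublets kept, these GC B-like values turned too. Reg3b was −0.39 (2.32) for adult HPD against juvenile HPD and −0.998 (0.90) for adult HPD DSS against juvenile HPD DSS. Fabp2 was −0.21 (1.53) for juvenile HPD DSS against juvenile SD DSS, and Fabp6 −0.65 (1.31) for adult HPD against adult SD. Ighg3 was 0.13 (−2.04) for juvenile HPD DSS against juvenile HPD, and Muc3 0.39 (−2.23) for adult SD DSS against adult SD. Pkm with DSS, follicular B-like (0.17) was −0.033 with classes from marker scores. Pkm with DSS, GC B-like (0.15) was −0.13 with classes from marker scores. Lgals4 with age, T-like (2.08) was −1.37 with free RNA subtracted.

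With the T-like share subtracted, the IgA difference with age was −2.06 points (reported 5.10). As a share of B-lineage cells, age in GC B-like cells was 0.86 (−1.62), age in plasma-like cells was 1.76 (−0.72), diet in GC B-like cells was 0.61 (−0.47), diet in plasma-like cells was 0.66 (−0.42) and DSS in plasma-like cells was 1.15 (−0.34). As a share of cells outside epithelial-like and unnamed clusters, age in plasma-like cells was 0.86 (−0.72), age in T-like cells was 0.85 (−0.73) and DSS in plasma-like cells was 0.14 (−0.34). edgeR on numbers of cells gave −3.06 for age in follicular B-like cells, past its threshold. The interferon median of juvenile HPD against juvenile SD in GC B-like cells (−1.21) was −0.88 with at least 1000 UMIs and −1.34 with at least 20. That of adult HPD against adult SD in follicular B-like cells (0.85) was 1.33 with at least 20 UMIs.

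Each library was left out in turn, and the ranges are from the lowest to the highest value. Gene counts ran for age 14 to 93 (60), diet 0 to 71 (5), DSS 5 to 29 (9), age by diet 0 to 57 (0), age by DSS 0 to 58 (0), diet by DSS 1 to 82 (2) in follicular B-like cells, age 3 to 38 (14), diet 4 to 26 (14), DSS 0 to 16 (2), age by diet 2 to 75 (18), age by DSS 0 to 29 (0), diet by DSS 0 to 72 (4) in GC B-like cells and age 88 to 938 (374), diet 0 to 80 (1), DSS 7 to 31 (39) in T-like cells. List counts ran for DSS 5 to 11 (10) in follicular B-like cells and age 7 to 16 (13), diet 6 to 11 (11), DSS 4 to 10 (11) in GC B-like cells. Values that turned sign without some library ran for the share with age, plasma-like, −1.09 to 0.049 (−0.72), the share with diet, GC B-like, −1.23 to 0.44 (−0.47), the share with DSS, plasma-like, −0.71 to 0.45 (−0.34), the IgA share with age, GC B-like, −5.99 to 12.5 (5.10), Stat1 with age, follicular B-like, −0.70 to 0.21 (−0.19), Pkm with age, follicular B-like, −0.012 to 0.38 (0.21), Pkm with diet, follicular B-like, −0.14 to 0.16 (0.052), Stat1 with DSS, follicular B-like, −0.45 to 0.36 (−0.028), Pkm with DSS, follicular B-like, −0.025 to 0.35 (0.17), Pkm with age, GC B-like, −0.15 to 0.16 (−0.0077), Pkm with DSS, GC B-like, −0.050 to 0.33 (0.15) and Stat1 with DSS, T-like, −0.64 to 0.0030 (−0.35). The lone partner of a library left out is assumed to vary like the other libraries. The fewest cells were 24 (GC B-like, adult SD DSS) and 39 (follicular B-like, adult HPD DSS).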

Other observations

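Epithelial-like droplets are not B cells, but they differ between libraries in ways that touch the transcripts seen elsewhere, and the genes named here were chosen after the clusters were seen. Cluster 7 (3216 cells, 95.8% from adult HPD DSS) held 6206 CPM of the lipid transport gene Apoa4, 12.5 of Gata4 and 1171 of the ileal bile acid gene Fabp6. Cluster 3, with cells of several libraries, held 27.7, 2.91 and 44681 CPM of the same genes. Cluster 11 came to 91.0% and cluster 27 to 99.3% from adult HPD DSS.

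Cluster 8 (2782 cells, 95.4% from juvenile HPD DSS) held 7378 CPM of the acute phase gene Saa1, 76372 of the antimicrobial gene Reg3b, 891 of Nos2 and 619 of the chemokine gene Ccl20, against 444, 29153, 247 and 4.51 in cluster 3. These clusters come almost from single libraries, so no test compares them.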
